A study of Arabidopsis thaliana with 18 samples.

How the data were processed

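The data are 18 libraries of root tips of Arabidopsis thaliana in 7 groups, set by whether the tips were cut, whether they received L-Kyn (L-kynurenine, an inhibitor of auxin synthesis from tryptophan) and the time of treatment. Seedlings were 7 days old per the labels. Cut root meristems were dissected 120 µm above the quiescent centre (QC), L-Kyn was given at 100 µM for 3 h or 6 h, and libraries were made with a 3′ kit that reads the ends of transcripts, per the labels. For mock cut tips the labels give the hours as time after the cut, and for L-Kyn tips as time of L-Kyn treatment. The labels' text on the treatment is incomplete, so whether L-Kyn was given before, at or after the cut is not known here. Cutting with L-Kyn stands for cut against uncut L-Kyn tips with the same hours. The title of L-Kyn uncut 6 h replicate 1 says uncut and its source field says cut, and the title was used. Its Spearman correlation over genes was 0.951 with L-Kyn uncut 6 h replicate 2, and 0.894 to 0.911 with the L-Kyn cut 6 h libraries. The values of that library thus lie nearer those of L-Kyn uncut than of L-Kyn cut tips at 6 h. Nothing in the labels says that replicates came from separate pools of seedlings, so p-values measure only the spread between these libraries, which may be technical.

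The authors deposited a table of read counts per locus, not normalised. Bowtie2, HTSeq and DESeq2 and the build TAIR10 are named in the submitters' processing notes, and their versions are not given in the sources used here. The table holds 22093 loci and 3 lines of the counting tool that name no gene, which were left out of library sizes and tests. Of a library's table total, 46.4% to 83.2% was counted as low alignment quality, 3.75% to 15.1% as no feature and 0.0918% to 0.329% as ambiguous. The smallest total of a locus over the libraries is 5 counts. Reads on genes ran from 1280947 to 4839810 per library, so that a floor of 3 counts is 0.620 to 2.34 CPM. Floors cover counting error only, as no molecular identifiers were used here. The table totals of 14 libraries lie between 11161330 and 11161938, and those of the other 4 between 3562797 and 7757873.

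Symbols came from a RefSeq gene table of assembly TAIR10.1, in which 21793 of the loci were found, and no coordinates were used because the builds differ. Near-identical genes can share reads, which makes values of KIN1 and KIN2, the RBCS, LHCB, AOC and glutathione transferase genes and UBQ10 uncertain.

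Each comparison was a contrast in an edgeR quasi-likelihood fit to the counts of all 18 libraries, with a mean per group, TMM factors, edgeR's expression filter by group (16354 genes) and Benjamini-Hochberg adjustment at 0.05 within a comparison. CPM values (counts scaled to library size) carry the TMM factors. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

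Gene lists, comparisons and a first group of other settings were fixed before the data were examined. The 18 lists were tested in 11 comparisons with limma's camera on log2 CPM (prior count of 2, preset correlation of 0.01), adjusted over the lists of a comparison. Lists described as lower or higher were called by camera at the preset correlation. Camera with an estimated correlation and fry were run beside it. Of 198 list tests, camera called 62 at the preset and 0 at the estimated correlation in the fit of all 18 libraries. Of 313 list members written down, 10 were dropped because their symbol did not match the reference. Genes were named by a fixed rule. It takes the 5 higher and 5 lower genes with the largest change among those called, with at least 10 CPM, no overlap between libraries and a symbol, and up to 4 called members of each list, at most 20 list members in a comparison. It also takes a panel of auxin, stem cell and cell cycle genes whatever their p. Genes outside it are named in the text as chosen after their values were seen. Not every gene that the rule takes is reported here.

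A pair of features was found after seeing the data. The libraries fall into 2 sets in the order of the table, set A with mock uncut replicates 1 and 2 and all 6 h libraries, and set B with mock uncut replicate 3 and all 3 h libraries. The library labelled L-Kyn cut 3 h replicate 2 has values near those of uncut tips. A set-matched fit adds a term for the set and leaves that library out (16934 genes). The term is estimated from mock uncut tips alone, replicate 3 against replicates 1 and 2. It may thus take in a deviation of replicate 3 itself that is not shared by set B. In the set-matched fit mock uncut tips give 1 library to the 3 h comparisons and L-Kyn cut tips at 3 h have 1 library, which is assumed to vary like the others. The rule for named genes was applied to that fit too.

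Alternatives were RLE factors, DESeq2, no filter, a stricter filter (mean of 5 CPM), a replicate block, only the groups compared, and each library left out in turn, and, added after seeing the data, the set term, that library left out, both together and each set alone. The edgeR fit was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. These counts had a common mean profile, no difference between the sets and no library unlike its label. The set-matched fit was not simulated. The shares below therefore do not cover false calls that these features of the real data may give. For cut against uncut mock tips at 3 h it called 55% of the 4-fold and 2% of the 2-fold changes among 15877 genes, with 8.06% of its calls false. At 6 h these values were 43% and 5% among 15881 genes, with 4% false. For L-Kyn against mock in uncut tips they were 63% and 3% among 15817 genes, with 2.94% false, at 3 h, and 31% and 1% among 15879 genes, with 3.03% false, at 6 h. In cut tips they were 28% and 0% among 15835 genes, with 12.5% false, at 3 h, and 30% and 1% among 15856 genes, with 6.06% false, at 6 h. For cutting with L-Kyn they were 46% and 2% among 15849 genes, with 7.69% false, at 3 h, and 38% and 0% among 15852 genes, with 5% false, at 6 h.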

Results

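Gene counts were measured by 3′ RNA sequencing in root tips of Arabidopsis seedlings, cut or uncut, with mock treatment or L-Kyn (L-kynurenine, an inhibitor of auxin synthesis). Mock uncut tips had 3 libraries with no time in the labels. Cut mock tips had 3 libraries at 3 h and 2 at 6 h, L-Kyn uncut tips had 3 at 3 h and 2 at 6 h, and L-Kyn cut tips had 2 at 3 h and 3 at 6 h. Reads on genes ranged from 1280947 in L-Kyn cut 6 h replicate 2 to 4839810 in L-Kyn cut 3 h replicate 1. They lay between 2198427 and 3223903 in mock uncut tips, between 1719910 and 2148525 in mock cut tips at 3 h, and between 1565197 and 2279217 in mock cut tips at 6 h. They lay between 1289289 and 4790142 in L-Kyn uncut tips at 3 h, between 2943056 and 3856837 at 6 h, between 4714282 and 4839810 in L-Kyn cut tips at 3 h and between 1280947 and 4503955 at 6 h. The libraries lie in 2 sets of 9, set A with mock uncut replicates 1 and 2 and the 6 h libraries, and set B with mock uncut replicate 3 and the 3 h libraries.

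The first comparison asked what cutting changes in mock tips at 3 h. Mock uncut tips, with no time in the labels, were the control at 3 h and 6 h. Hours elapsed or time of sampling thus cannot be told apart from cutting in mock tips, or from L-Kyn in uncut tips. Between L-Kyn and mock cut tips the time after the cut may differ, as the labels give it for mock cut tips alone. The labels place the cut above the quiescent centre. Whether the pieces collected as cut tips held tissue from below the cut is not known here. A fall in root cap, stem cell, auxin synthesis, mitotic or DNA replication genes in cut tips may reflect loss of tissue, lower expression or both. These were not tested apart, with mock or L-Kyn, at 3 h or 6 h. WOX5 (AT3G11260), the homeobox gene of the quiescent centre (QC), rose 15.4-fold (log2 fold change 3.94 ± 0.87 SE, edgeR adjusted p = 0.0116), from 1.32 ± 1.37 to 21.7 ± 7.37 CPM (counts scaled to library size, SD, n = 3 each). Its log2 fold change ran from 3.56 without mock uncut replicate 1 to 5.21 without mock uncut replicate 3. The root cap cellulase gene CEL5 (AT1G22880) fell from 99.8 ± 92.6 to 0.847 ± 0.463 CPM, and the stem cell regulator PLT1 (AT3G20840) fell from 28.9 ± 6.39 to 1.21 ± 2.09 CPM. YUC3 (AT1G04610), an auxin synthesis gene, fell from 28.8 ± 13.4 to 1.5 ± 2.10 CPM. RGF3 (AT2G04025), a peptide gene of the meristem, fell from 66.3 ± 26.6 CPM to 0 counts in the cut tips, and RGF2 (AT1G13620) of the same family fell from 27.4 ± 12 to 0.201 ± 0.349 CPM.

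EdgeR's quasi-likelihood test called 1618 genes, 653 higher and 965 lower, and DESeq2 called 2259. Of 8 measured root cap genes, 4 fell and 1 rose, or 5 and 1 adjusted over the list alone (median log2 fold change -2.61, camera adjusted p = 0.00434, and adjusted p = 0.240 with an estimated correlation). The member that rose, ARF16 (AT4G30080), is an auxin response factor, named after its values were seen (log2 fold change 2.12 ± 0.54 SE, edgeR adjusted p = 0.0231). Of 12 stem cell niche genes, 4 fell and 1, WOX5, rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0421, and adjusted p = 0.264 with an estimated correlation). That call was lost without mock cut 3 h replicate 1 or 3 or mock uncut replicate 1 or 2 (camera adjusted p = 0.0936, 0.140, 0.0736 and 0.0903). Of 21 mitotic genes, 16 fell and 0 rose, or 17 lower adjusted over the list alone (median -2.63, camera adjusted p = 3.04e-12, and adjusted p = 0.240 with an estimated correlation). The B-type cyclin genes CYCB1;4 (AT2G26760) and CYCB2;2 (AT4G35620) fell 13.3-fold (log2 fold change -3.74 ± 0.62 SE) and 12.6-fold, and CDKB2;2 (AT1G20930), a mitotic kinase gene, fell 5.96-fold. CYCB1;1 (AT4G37490) fell 8.27-fold (adjusted p = 0.0357). The log2 fold change of CYCB1;1, -3.05, was -2.40 and -4.96 without mock cut 3 h replicate 1 and 2. That of CYCB1;4 was -4.37 without mock cut 3 h replicate 3, and that of CDKB2;2, -2.57, was -1.98 without mock uncut replicate 3. Of 15 DNA replication genes, 2 fell, or 5 adjusted over the list alone (median -0.72, and adjusted p = 0.240 with an estimated correlation).

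Genes of wounding, touch and jasmonate were higher. Of 18 early stress and touch genes, 5 rose and 0 fell, or 12 higher adjusted over the list alone (median 2.01, and adjusted p = 0.240 with an estimated correlation). TCH3 (AT2G41100), a calmodulin-like touch gene, rose 15.7-fold, from 17.1 ± 14.5 to 269 ± 52.1 CPM, and CML39 (AT1G76640), also calmodulin-like, rose 4.72-fold. Of 16 regeneration regulators, 4 rose, or 7 adjusted over the list alone (median 1.63, and adjusted p = 0.240 with an estimated correlation). Among them the NAC factor ANAC096 (AT5G46590) rose 8.87-fold, the Dof factor HCA2 (AT5G62940) rose 7.26-fold and the GRAS factor PAT1 (AT5G48150) rose 3.43-fold. Of 11 jasmonate genes, 3 rose, or 8 adjusted over the list alone (median 2.44, and adjusted p = 0.240 with an estimated correlation). LTI78 (AT5G52310), a drought and cold gene, rose 69.1-fold (log2 fold change 6.11 ± 1.21 SE, adjusted p = 0.00727), with 5.49 without mock uncut replicate 3 and 7.01 without replicate 1. The log2 fold change of TCH3, 3.97, was 4.82 without mock uncut replicate 1, and that of ANAC096, 3.15, was 2.37 without mock cut 3 h replicate 1. With 1 library left out the jasmonate median was below 2.44 in each case. It ran from 1.23 without mock cut 3 h replicate 1 to 1.87 without mock uncut replicate 1. The regeneration median was 0.91 without mock cut 3 h replicate 3.

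At 3 h the called members of the 4 auxin lists fell, and they came from 3 of these lists. LAX2 (AT2G21050), an auxin influx carrier, fell 7.37-fold, from 67.9 ± 8.36 to 9.23 ± 3.67 CPM, and CYP79B2 (AT4G39950), an enzyme of indole-3-acetaldoxime synthesis, fell 12.6-fold. The log2 fold change of CYP79B2, -3.65, was -5.02 without mock cut 3 h replicate 1. The auxin transport list (2 of 12 lower, the same count adjusted over the list alone) and the tryptophan and indolic list (3 of 13 lower, or 4 adjusted over the list alone) were not called by camera (adjusted p = 0.548 and 0.548). Neither was the TAA and YUCCA list (1 of 6 lower, or 1 adjusted over the list alone, camera adjusted p = 0.548) or the auxin-responsive list (0 of 13 lower and 0 higher, or 0 and 0 adjusted over the list alone, camera adjusted p = 0.779). TAA1 (AT1G70560), the aminotransferase that L-Kyn inhibits, was at 10.6 ± 5.62 CPM in uncut and 18.8 ± 6.25 CPM in cut tips, with no call.

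Green tissue genes differed as well, with 8 of 10 lower, the same count adjusted over the list alone (median -4.28, and adjusted p = 0.240 with an estimated correlation). They followed the library set, RBCS1A (AT1G67090) being at 91.3 and 37.8 CPM in mock uncut replicates 1 and 2 of set A, and at 0 CPM in replicate 3 of set B. In the set-matched fit, chosen after seeing the data, which has a term for the set and leaves out the library labelled L-Kyn cut 3 h replicate 2, 1906 genes were called (1067 higher, 839 lower), and within set B alone 537, in each case against 1 mock uncut library. WOX5 rose 7.35-fold in the set-matched fit (edgeR adjusted p = 0.0356), and the mitotic, stress and regeneration lists were called (adjusted p = 0.00534, 0.0146 and 0.0146 with an estimated correlation). The stem cell niche, DNA replication and green tissue lists were not called there (camera adjusted p = 0.0523, 0.0523 and 0.374). The edgeR count was 557 without mock uncut replicate 2, 643 without mock cut 3 h replicate 1, 801 without mock uncut replicate 1, 806 without mock cut 3 h replicate 2 and 2467 without mock uncut replicate 3. In the last setting the mock uncut libraries are all of set A and the mock cut 3 h libraries of set B. Its count thus cannot tell cutting from the set. TCH3 lost its call without mock uncut replicate 2 (adjusted p = 0.0520), PLT1 and ANAC096 without mock cut 3 h replicate 1 (adjusted p = 0.0574 and 0.0603), and CYCB1;1 without mock cut 3 h replicate 1 or 3 or mock uncut replicate 1 or 2 (adjusted p = 0.115, 0.0764, 0.0595 and 0.0620). With the set term alone WOX5, ANAC096, HCA2, CML39 and PAT1 lost their calls (edgeR adjusted p = 0.113, 0.0932, 0.0504, 0.0562 and 0.104), PAT1 in the set-matched fit too (adjusted p = 0.0821). Within set B alone these genes and CYCB1;1 lost them (in that order, adjusted p = 0.0549, 0.0998, 0.0994, 0.0988, 0.189 and 0.0710). With only the groups compared HCA2, CML39, PAT1, CDKB2;2 and CYCB1;1 lost them (adjusted p = 0.0550, 0.0677, 0.0734, 0.0536 and 0.103).

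**Figure D1:**
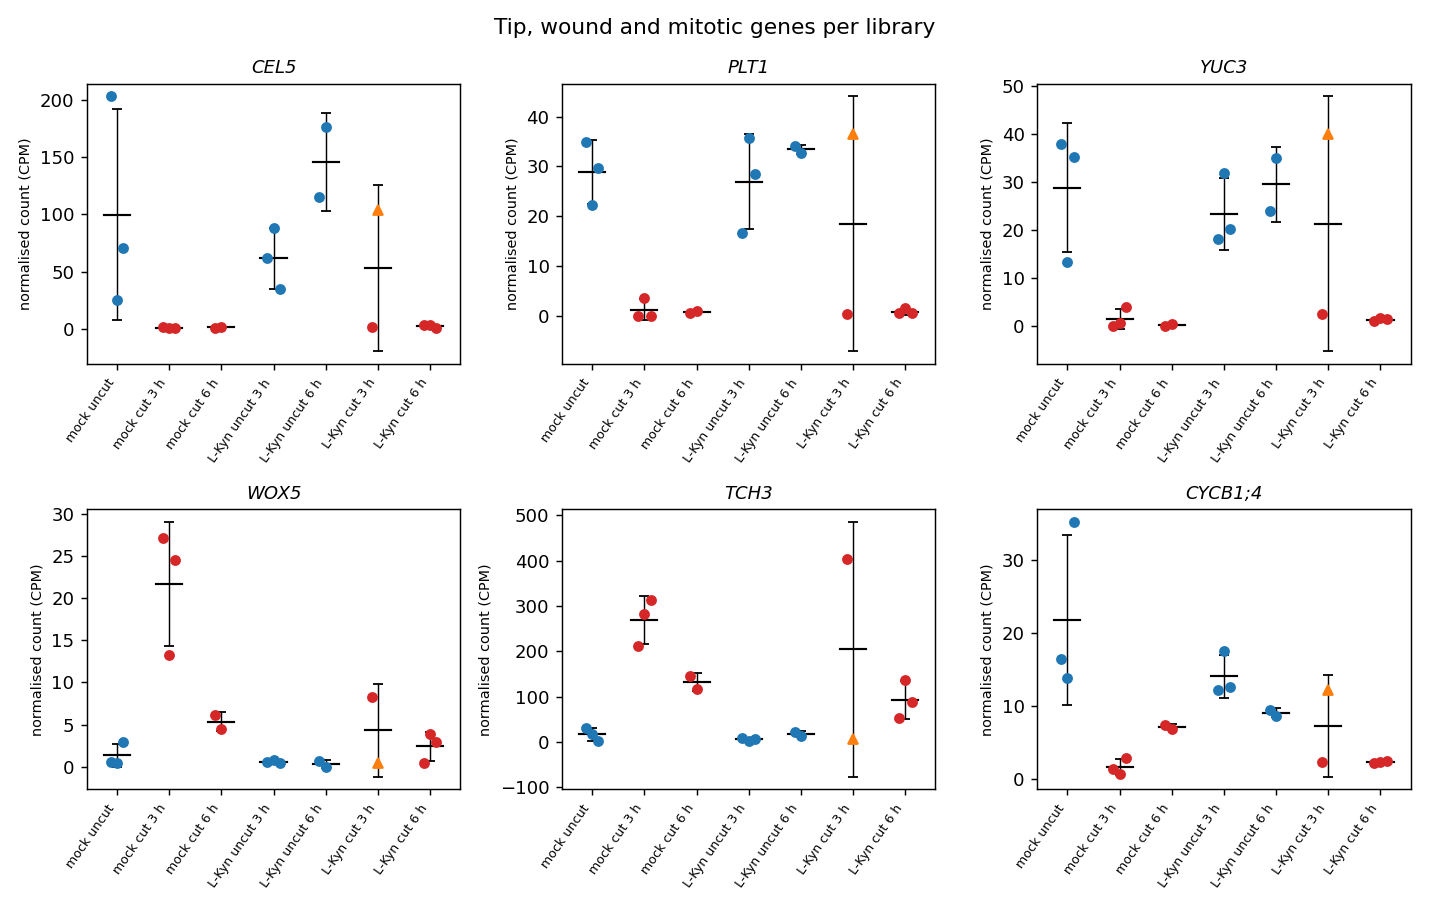
Normalised counts (CPM, y axis) of 6 genes in each of the 7 groups (x axis), with a point per library (blue uncut, red cut, orange triangle the library labelled L-Kyn cut 3 h replicate 2), a bar at the mean and whiskers of 1 SD. PLT1 lies at 28.9 CPM on average in mock uncut tips and 1.21 CPM in mock cut tips at 3 h, and the triangle lies at 36.6 CPM.

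At 6 h after cutting, root cap and auxin synthesis genes were lower as lists and regeneration genes higher in mock tips, with no gene called over all genes tested. The root cap list had 7 of 8 members with a negative sign (median -2.67, camera adjusted p = 4.67e-05, and adjusted p = 0.103 with an estimated correlation), and 4 were lower adjusted over the list alone. The TAA and YUCCA list had 5 of 6 members with a negative sign (1 lower adjusted over the list alone, median -2.54, and adjusted p = 0.0969 with an estimated correlation). The regeneration list had 15 of 16 with a positive sign (1 higher adjusted over the list alone, median 1.2, and adjusted p = 0.103 with an estimated correlation). The stem cell niche list was lower (3 of 12 adjusted over the list alone, median -1.3, and adjusted p = 0.220 with an estimated correlation). So was the mitotic list (median -0.73, and adjusted p = 0.409 with an estimated correlation). Detoxification genes were higher (median 0.84, 7 of 19 adjusted over the list alone, and adjusted p = 0.103 with an estimated correlation), as were stress genes (median 0.93) and green tissue genes (median 0.52), both at adjusted p = 0.409 with an estimated correlation. Camera calls were lost for the stem cell niche list without mock cut 6 h replicate 1 or mock uncut replicate 2 (adjusted p = 0.163 and 0.0562). They were lost for the TAA and YUCCA list without mock uncut replicate 1 (adjusted p = 0.0622), and for the green tissue list without mock cut 6 h replicate 2 or mock uncut replicate 3 (adjusted p = 0.211 and 0.443). The TAA and YUCCA median was -1.55 and -0.65 without mock uncut replicate 1 and 3, and the mitotic median was -0.43 without mock uncut replicate 3. The green tissue median was 0.98 and -0.01 without mock cut 6 h replicate 1 and 2, and 1.84 and 0.34 without mock uncut replicate 1 and 2.

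EdgeR called 0 genes at 6 h, DESeq2 34, and 1594 had an unadjusted p under 0.05. Without mock uncut replicate 3 edgeR called 1. In the set-matched fit 31 genes rose and 62 fell, and within set A alone 217 were called. In that fit the cold-induced genes KIN2 (AT5G15970) and KIN1 (AT5G15960), near-identical copies whose shares of reads are uncertain, rose 17.4-fold and 24.0-fold, to 3071 ± 24.0 and 394 ± 4.50 CPM (n = 2). The ribonuclease gene RNS1 (AT2G02990) rose 16.9-fold, the nuclease gene ENDO2 (AT1G68290) 15.4-fold and TCH3 5.22-fold. LAX2 fell 4.08-fold, CEL5 88.2-fold and ACL5 (AT5G19530), a vascular gene, 8.01-fold. WOX5 was at 5.34 ± 1.16 CPM in cut tips at 6 h, with no call. The regeneration list was called in that fit (adjusted p = 0.0138 with an estimated correlation) and the green tissue list was not (camera adjusted p = 0.352).

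Between 3 h and 6 h after cutting, 94 genes rose and 9 fell in mock tips, and DESeq2 called 293. LHY (AT1G01060), a clock gene, fell 9.33-fold (log2 fold change -3.22 ± 0.69 SE, edgeR adjusted p = 0.0386), from 17.1 ± 9.98 (n = 3) to 1.75 ± 0.726 CPM (n = 2). HDR (AT4G34350), of the plastid isoprenoid pathway, fell 3.51-fold, and BTI1 (AT4G23630), a reticulon gene, fell 2.93-fold. Among the genes that rose, HCAR (AT1G04620), of chlorophyll turnover, went from 0.604 ± 1.05 to 53.7 ± 5.04 CPM. The mitotic list was higher at 6 h (19 of 21 with a positive sign, 10 adjusted over the list alone, median 1.70, and adjusted p = 0.25 with an estimated correlation). The tryptophan and indolic list was higher too (2 of 13 adjusted over the list alone, median 0.40, and adjusted p = 0.25 with an estimated correlation). So was the detoxification list (4 of 19 adjusted over the list alone, median 0.54, and adjusted p = 0.405 with an estimated correlation). The stress and jasmonate lists were lower (medians -0.76 and -0.75, and adjusted p = 0.470 and 0.348 with an estimated correlation). Without mock cut 3 h replicate 3 camera lost the stress, jasmonate and tryptophan calls (adjusted p = 0.158, 0.112 and 0.0986). It lost the jasmonate and tryptophan calls without mock cut 3 h replicate 2 (adjusted p = 0.0598 for both) and the jasmonate call without mock cut 6 h replicate 1 (adjusted p = 0.0966). The tryptophan median was 0.63 without mock cut 3 h replicate 3.

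The libraries of these groups lie in different sets, and 5 of 10 green tissue genes were among those that rose, or 9 adjusted over the list alone (median 5.37, and adjusted p = 0.222 with an estimated correlation). A fit with a set term tests the difference between both responses to cutting, and edgeR called 12 genes with that term alone. With the term and without the library labelled L-Kyn cut 3 h replicate 2 (the set-matched fit) 29 genes were higher and 121 lower. In the latter fit CYP83B1 (AT4G31500), of indole glucosinolate synthesis, and CYP79B2 differed by 5.08 and 4.06 on the log2 scale, the cyclin genes CYCB2;2 and CYCB1;4 by 3.80 and 3.3, and TCH3 by -4.29. The mitotic list was called there (adjusted p = 0.0212 with an estimated correlation), and the detoxification and green tissue lists were not (camera adjusted p = 0.602 and 0.264), with a detoxification median of -0.30. The count of 103 was 1 and 6 without mock cut 6 h replicate 1 and 2, and 27, 4 and 48 without mock cut 3 h replicate 1, 2 and 3. LHY lost its call without any of these but mock cut 3 h replicate 3 (adjusted p = 0.0888, 0.149, 0.325 and 0.296 for mock cut 3 h replicates 1 and 2 and 6 h replicates 1 and 2). BTI1 lost its call without the same libraries (adjusted p = 0.0567, 0.171, 0.393 and 0.364), and HDR without mock cut 3 h replicate 2 or either 6 h library (adjusted p = 0.0992, 0.228 and 0.215). LHY, BTI1 and HDR also lost their calls with the set term alone (adjusted p = 0.243, 0.138 and 0.128), in the set-matched fit (adjusted p = 0.220, 0.0822 and 0.0693) and with only the groups compared (adjusted p = 0.152, 0.130 and 0.0527). With the replicate number as a block LHY and BTI1 lost them (adjusted p = 0.0668 and 0.0704).

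The next comparisons asked what L-Kyn changes in uncut tips. Auxin-responsive genes were lower as a list at both times in the fit of all 18 libraries, but the set-matched fit called the list at 6 h only. At 3 h, 11 of 13 had a negative sign, 4 of them lower adjusted over the list alone (median -1.27, camera adjusted p = 0.000163, and adjusted p = 0.295 with an estimated correlation). At 6 h, 11 of 13 had a negative sign, 2 lower adjusted over the list alone (median -1.11, camera adjusted p = 0.00363, and adjusted p = 0.213 with an estimated correlation). The AUX/IAA gene IAA1 (AT4G14560) was at 20.8 ± 1.62 CPM in mock uncut tips, 3.78 ± 4.13 with L-Kyn at 3 h (n = 3 each) and 5.07 ± 0.963 at 6 h (n = 2). IAA4 (AT5G43700) was at 22.9 ± 4.05, 7.86 ± 4.97 and 6.77 ± 3.84 CPM, and IAA19 (AT3G15540) at 6.41 ± 0.901, 0.660 ± 1.14 and 1.03 ± 0.981 CPM in the same groups. TAA1 was at 6.21 ± 0.536 CPM at 3 h and 5.46 ± 0.398 CPM at 6 h. None of these genes was called over all genes tested. At 6 h the auxin list lost its call without L-Kyn uncut 6 h replicate 1 or mock uncut replicate 1 (camera adjusted p = 0.103 and 0.0958), and its median was -0.62 without L-Kyn uncut 6 h replicate 2. IAA1 and IAA4 were chosen after their values were seen, as were UGT74E2 and GSTU24 for these tips.

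Detoxification genes were higher in L-Kyn uncut tips. At 6 h 17 of 19 had a positive sign, 9 higher adjusted over the list alone (median 0.69, camera adjusted p = 3.11e-07, and adjusted p = 0.0807 with an estimated correlation). At 3 h 6 were higher and 1 lower adjusted over the list alone (median 0.38, and adjusted p = 0.295 with an estimated correlation). UGT74E2 (AT1G05680), a glucosyltransferase gene, was at 83.0 ± 38.3 CPM in mock uncut tips, 224 ± 139 with L-Kyn at 3 h and 340.0 ± 81.4 at 6 h, and GSTU24 (AT1G17170), a glutathione transferase gene, was at 100.4 ± 15.6, 310.5 ± 71.4 and 234 ± 3.85 CPM. At 6 h the cytokinin and vascular lists were lower (medians -0.34 and -1.11, 2 of 9 and 2 of 13 adjusted over the list alone, and adjusted p = 0.0807 for both with an estimated correlation). The vascular list shares the members TMO5 and ATHB8 with the auxin-responsive list, which had the same median at 6 h, so their falls are not independent. The mitotic list was lower as well (median -0.66, and adjusted p = 0.827 with an estimated correlation). At 3 h the ethylene and DNA replication lists were lower (medians -1.29 and -0.38, and adjusted p = 0.295 for both with an estimated correlation). Green tissue genes had a median of -2.76 at 3 h, 8 of 10 lower adjusted over the list alone, and 1.28 at 6 h (adjusted p = 0.295 and 0.213 with an estimated correlation). Without mock uncut replicate 3 camera lost the 3 h calls of the detoxification, DNA replication and ethylene lists (adjusted p = 0.226, 0.121 and 0.226). It lost the DNA replication call without L-Kyn uncut 3 h replicate 2 (adjusted p = 0.118) and the ethylene call without L-Kyn uncut 3 h replicate 1, 2 or 3 or mock uncut replicate 1 (adjusted p = 0.150, 0.0529, 0.149 and 0.195). The 6 h mitotic call was lost without L-Kyn uncut 6 h replicate 1 or mock uncut replicate 2 or 3 (adjusted p = 0.168, 0.0641 and 0.149). The 3 h detoxification median was 0.23 without L-Kyn uncut 3 h replicate 2, and 0.58 and 0.17 without mock uncut replicate 1 and 3. The 3 h ethylene median was -0.48 and -0.36 without L-Kyn uncut 3 h replicate 1 and 3, and -0.44 and -0.25 without mock uncut replicate 1 and 3. The green tissue median was -1.68 at 3 h and 2.70 at 6 h without mock uncut replicate 1, and 0.81 at 6 h without mock uncut replicate 3. At 6 h the cytokinin and mitotic medians were -0.58 and -0.40 without mock uncut replicate 3, and the cytokinin median was -0.60 without L-Kyn uncut 6 h replicate 1. The vascular median was -0.62 without L-Kyn uncut 6 h replicate 2 and -0.59 without mock uncut replicate 1.

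EdgeR called 0 genes at 3 h (1480 with an unadjusted p under 0.05, and 118 by DESeq2) and 0 at 6 h (1393 with an unadjusted p under 0.05, and 57 by DESeq2). With mock uncut replicate 3 left out, L-Kyn at 3 h cannot be told apart from the set. The other mock uncut libraries are of set A and the L-Kyn uncut 3 h libraries of set B. Without mock uncut replicate 3 the 3 h count was 452, GSTU24 among them (adjusted p = 0.00518), and without L-Kyn uncut 6 h replicate 1 the 6 h count was 2. Within set B alone 3 genes were called at 3 h, and within set A alone 42 at 6 h. In the set-matched fit 22 genes were called at 3 h, against 1 mock uncut library, among them ALMT12 (AT4G17970), an anion channel gene, which rose from 0.643 CPM in that library to 19.1 ± 9.14 CPM (n = 3). It called 1 at 6 h, EMB1030 (AT5G22800), which rose 22.9-fold, from 5.54 ± 1.96 to 131 ± 48.2 CPM (n = 2 each, edgeR adjusted p = 0.0246). In that fit the auxin-responsive list was not called at 3 h (camera adjusted p = 0.157, with green tissue, ethylene and DNA replication at 0.784, 0.0955 and 0.226). It was called at 6 h (camera adjusted p = 0.00487, and adjusted p = 0.321 with an estimated correlation), and the cytokinin list was called at 6 h (adjusted p = 0.0314 with an estimated correlation).

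**Figure D2:**
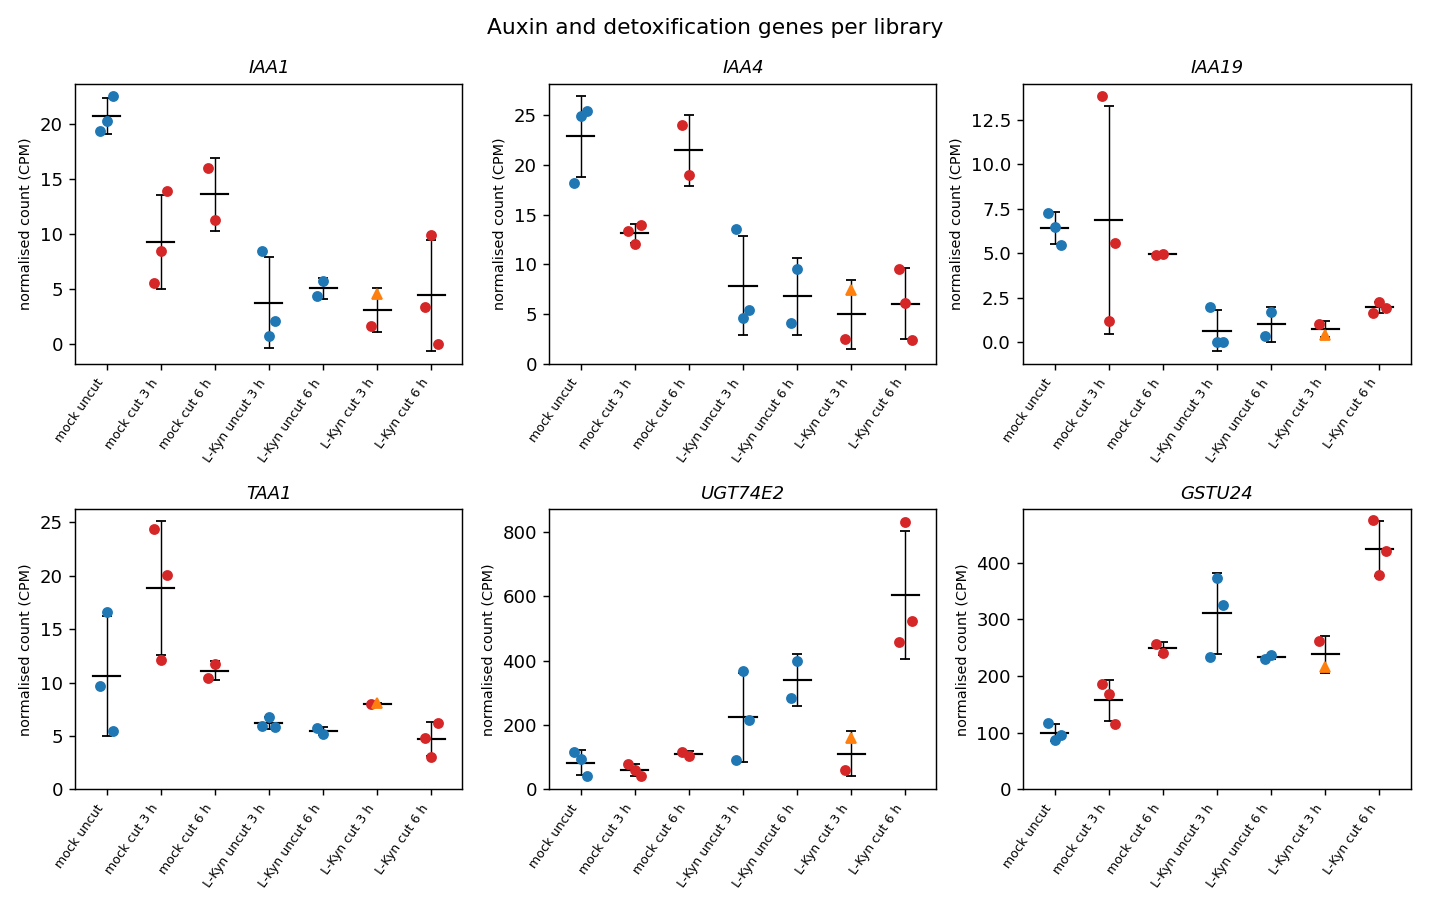
Normalised counts (CPM, y axis) of 6 genes in each of the 7 groups (x axis), drawn as in the plot of tip, wound and mitotic genes. IAA1 lies at 20.8 CPM on average in mock uncut tips and 3.78 and 5.07 CPM in L-Kyn uncut tips at 3 h and 6 h.

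In cut tips at 6 h, mitotic genes were lower and detoxification genes higher with L-Kyn than with mock. All 21 measured mitotic genes had a negative sign, 7 of them lower adjusted over the list alone (median -1.81, camera adjusted p = 1.67e-11, and adjusted p = 0.316 with an estimated correlation). Of 19 detoxification genes, 17 had a positive sign, 5 higher adjusted over the list alone (median 0.77, and adjusted p = 0.287 with an estimated correlation). The auxin-responsive list was lower (10 of 13 with a negative sign, 2 lower adjusted over the list alone, median -0.60) and the ethylene list higher (1 adjusted over the list alone, median 0.79), both at adjusted p = 0.360 with an estimated correlation. In the set-matched fit 17 genes rose and 2 fell, and within set A alone 55 were called. In that fit EMB1030 rose 19.7-fold (log2 fold change 4.30 ± 0.75 SE, edgeR adjusted p = 0.0146), the gibberellin oxidase gene GA2OX2 (AT1G30040) 8.06-fold and the ABC transporter gene ABCC3 (AT3G13080) 7.02-fold. UGT74E2 rose 5.64-fold, from 108 ± 9.28 (n = 2) to 611 ± 206 CPM (n = 3), and ABCB4 (AT2G47000), an auxin transporter, rose 3.62-fold. UBQ10 (AT4G05320), a polyubiquitin gene whose value is uncertain because its relatives can share reads, rose 3.99-fold, and HDT4 (AT2G27840), a histone deacetylase gene, fell 3.51-fold. The mitotic list was called in that fit (13 lower adjusted over the list alone, median -1.76, and adjusted p = 0.00373 with an estimated correlation). In the fit of all 18 libraries the auxin-responsive and ethylene medians were -0.38 and 0.52 without L-Kyn cut 6 h replicate 1. The ethylene median was 0.25 without L-Kyn cut 6 h replicate 2 and 0.46 without mock cut 6 h replicate 2.

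In the fit of all 18 libraries edgeR called 0 genes in this comparison (1263 with an unadjusted p under 0.05), and DESeq2 48. EdgeR called 3 with the set term alone, 2 when only the library labelled L-Kyn cut 3 h replicate 2 was left out, and 37 with only the groups compared. TAA1 was at 11.1 ± 0.902 CPM in mock cut and 4.69 ± 1.59 CPM in L-Kyn cut tips at 6 h, and WOX5 at 5.34 ± 1.16 and 2.39 ± 1.72 CPM, with no call for either. Without L-Kyn cut 6 h replicate 1 camera lost the auxin-responsive and ethylene calls (adjusted p = 0.0897 and 0.0850), and it lost the ethylene call without L-Kyn cut 6 h replicate 2 or mock cut 6 h replicate 2 (adjusted p = 0.121 and 0.124).

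At 3 h the pair of L-Kyn cut libraries differed from each other. PLT1 was at 0.421 CPM in replicate 1 and 36.6 CPM in the library labelled replicate 2, CEL5 at 1.68 and 104 CPM, TCH3 at 403 and 5.17 CPM, and WOX5 at 8.21 and 0.413 CPM. Against mock cut tips, auxin-responsive genes were lower as a list (11 of 13 with a negative sign, 2 lower adjusted over the list alone, median -0.65, camera adjusted p = 0.00793, and adjusted p = 0.366 with an estimated correlation). The cytokinin and jasmonate lists were lower (medians -0.49 and -0.33) and the mitotic list higher (12 adjusted over the list alone, median 1.67), all at adjusted p = 0.366 with an estimated correlation. The mitotic median was -0.48 and the jasmonate median 0.03 in the set-matched fit, which leaves the library labelled replicate 2 out, and neither list was called there (camera adjusted p = 0.101 and 0.677). The auxin-responsive list was called in it (camera adjusted p = 0.000105, and adjusted p = 0.119 with an estimated correlation). EdgeR called 0 genes (1282 with an unadjusted p under 0.05, and 39 by DESeq2). Without replicate 1 the group holds only the library labelled replicate 2, whose values lie near those of uncut tips. WOX5 had a log2 fold change of -5.55 in that setting, which may therefore not reflect L-Kyn in cut tips. It was -1.40 without the library labelled replicate 2. Without L-Kyn cut 3 h replicate 1 camera lost the auxin-responsive and cytokinin calls (adjusted p = 0.0669 and 0.167). It lost the auxin-responsive, cytokinin and jasmonate calls without mock cut 3 h replicate 3 (adjusted p = 0.158, 0.118 and 0.154) and the last pair without mock cut 3 h replicate 2 (adjusted p = 0.103 for both). Without the library labelled replicate 2 the jasmonate and mitotic lists had adjusted p = 0.692 and 0.0789. The auxin-responsive, jasmonate and mitotic medians were -0.42, -1.91 and 2.53 without replicate 1, and -1.05, 0.03 and -0.48 without the library labelled replicate 2. Without mock cut 3 h replicate 1 the cytokinin and jasmonate medians were -0.32 and -0.65.

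**Figure D3:**
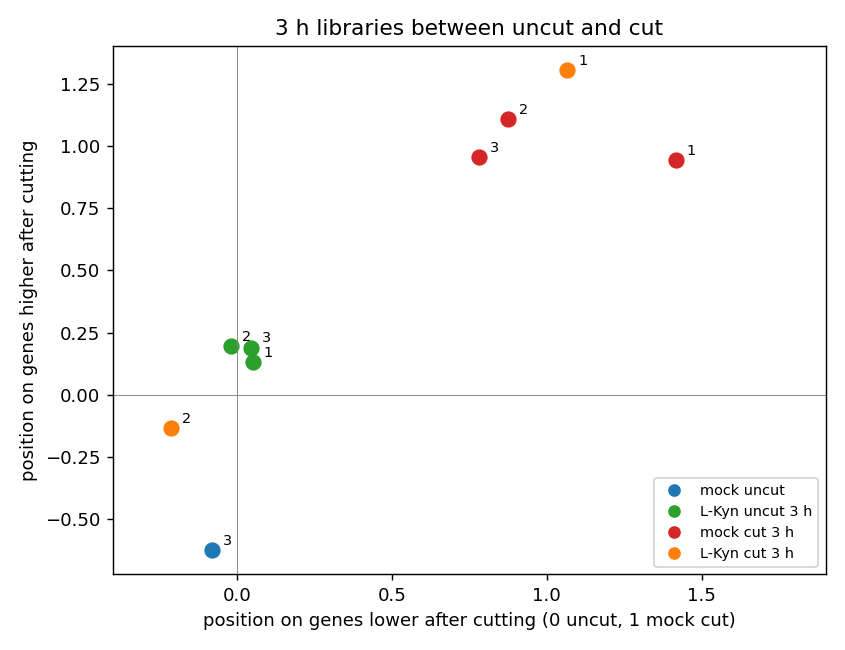
Position of each set B library on genes that were lower (x axis, 816 genes) and higher (y axis, 950 genes) in cut than in uncut L-Kyn tips at 6 h (mean log2 difference scaled so that 0 is the other uncut libraries of set B and 1 the mock cut ones, with replicate numbers beside the points). L-Kyn cut 3 h replicate 1 lies at 1.07 and 1.3, and the library labelled replicate 2 at -0.213 and -0.133. Mock uncut replicate 3 lies at -0.0793 and -0.624.

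Among L-Kyn tips at 6 h, cut tips had lower root cap, stem cell and mitotic genes and higher regeneration genes than uncut tips. EdgeR called 99 genes, 56 higher and 43 lower, and DESeq2 707. The trypsin inhibitor gene TI1 (AT2G43510) rose 97.2-fold (log2 fold change 6.60 ± 1.18 SE, edgeR adjusted p = 0.0276), from 1.76 ± 0.857 (n = 2) to 172 ± 40.7 CPM (n = 3), and KIN2 rose 41.2-fold. CEL5 fell 62.7-fold, SMB (AT1G79580), a root cap regulator, 22.0-fold, YUC3 23.4-fold, LAX2 7.20-fold and KN (AT1G08560), a syntaxin of cytokinesis, 8.42-fold. The log2 fold change of TI1 was 7.23 without L-Kyn uncut 6 h replicate 1, and that of KN, -3.07, was -3.70 without L-Kyn cut 6 h replicate 1. Of 8 root cap genes 2 fell (5 adjusted over the list alone, median -3.05), of 12 stem cell niche genes 3 (3, median -1.35), and of 6 TAA and YUCCA genes 1 (2, median -0.92). Each of these lists, the regeneration list (median 1.63, 6 of 16 higher adjusted over the list alone) and the detoxification list (median 1.00, 8 of 19 likewise) had adjusted p = 0.125 with an estimated correlation. Of 21 mitotic genes 2 fell (13 adjusted over the list alone, median -1.91, and adjusted p = 0.144 with an estimated correlation), and the DNA replication list was lower (median -0.54, and adjusted p = 0.190 with an estimated correlation). The stem cell niche and TAA and YUCCA medians were -0.46 and -1.63 without L-Kyn uncut 6 h replicate 2, and the stem cell niche median was -2.15 without L-Kyn cut 6 h replicate 3.

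The set-matched fit called 1138 genes (613 higher, 525 lower), and set A alone gave 1766. Of 21 mitotic genes 11 fell there and of 16 regeneration genes 6 rose, or 16 and 9 adjusted over the list alone, ANAC096 by 12.1-fold and the cell wall enzyme gene XTH19 (AT4G30290) by 7.40-fold. The regeneration, mitotic and root cap lists were called there (adjusted p = 0.00449, 0.00449 and 0.0305 with an estimated correlation). In the fit of all groups with no set term, the count of 99 was 0 without L-Kyn cut 6 h replicate 2 or 3 or L-Kyn uncut 6 h replicate 2, 21 without L-Kyn uncut 6 h replicate 1 and 25 without L-Kyn cut 6 h replicate 1. SMB, YUC3, LAX2 and KN lost their calls without each of these libraries, YUC3 at adjusted p = 0.0658 to 0.521, LAX2 at 0.0809 to 0.521 and KN at 0.0548 to 0.593 (SMB adjusted p = 0.0650, 0.107 and 0.167 for L-Kyn cut replicates 1, 2 and 3 and 0.0735 and 0.461 for L-Kyn uncut replicates 1 and 2). TI1 and KIN2 lost theirs without each but L-Kyn cut replicate 1, KIN2 at adjusted p = 0.0782 to 0.521 and TI1, in the same order of libraries, at adjusted p = 0.0980, 0.114, 0.0808 and 0.553. CEL5 lost its call without each but L-Kyn uncut replicate 1 (in that order, adjusted p = 0.0610, 0.0987, 0.167 and 0.315). The TAA and YUCCA list lost its camera call without L-Kyn cut 6 h replicate 1 (adjusted p = 0.0610). With the replicate number as a block, edgeR called 11 genes, and TI1, CEL5, SMB, YUC3, LAX2 and KN lost their calls (adjusted p = 0.0508, 0.0508, 0.0553, 0.0508, 0.0642 and 0.0553).

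At 3 h with L-Kyn, stress, jasmonate and regeneration genes were higher in cut tips. The stress list had 18 of 18 members with a positive sign, 12 higher adjusted over the list alone (median 2.20, and adjusted p = 0.0925 with an estimated correlation). The regeneration list (median 1.39, 6 of 16 higher adjusted over the list alone) had adjusted p = 0.0925, and the jasmonate and ethylene lists (medians 1.40 and 0.97, 4 of 11 and 1 of 9 higher adjusted over the list alone) adjusted p = 0.173, with an estimated correlation. The mitotic list was lower (median -0.74, and adjusted p = 0.0962 with an estimated correlation), as were the root cap and green tissue lists (medians -0.14 and -0.65, and adjusted p = 0.343 and 0.573 with an estimated correlation). EdgeR called 0 genes (492 with an unadjusted p under 0.05, and 57 by DESeq2), 339 without the library labelled L-Kyn cut 3 h replicate 2, and within set B alone 262. Without L-Kyn cut 3 h replicate 1 camera lost the stress, regeneration, ethylene, jasmonate, mitotic and green tissue calls (adjusted p = 0.309, 0.944, 0.316, 0.672, 0.781 and 0.709) and turned the root cap list higher (adjusted p = 0.0244). The green tissue call was also lost without each of the other 4 libraries (adjusted p = 0.0576 without the library labelled L-Kyn cut replicate 2, and 0.0842, 0.0622 and 0.0758 without L-Kyn uncut replicates 1, 2 and 3). The root cap call was lost without L-Kyn uncut 3 h replicate 1 or 2 (adjusted p = 0.0824 and 0.0501). Medians without L-Kyn cut 3 h replicate 1 were 0.03, 0.18, 0.42, -0.09, 0.05, 0.60 and -0.03 for the stress, regeneration, ethylene, jasmonate, mitotic, root cap and green tissue lists. Without the library labelled replicate 2 they were 0.60, 2.20, -3.0, -3.06 and -1.71 for the last 5 of these. The root cap median was -0.22, 0.24 and -0.43 without L-Kyn uncut 3 h replicate 1, 2 and 3, and the green tissue median was -0.42 without L-Kyn uncut 3 h replicate 2.

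In the set-matched fit, where L-Kyn cut tips at 3 h have 1 library, 375 genes rose and 187 fell. TCH3 rose 68.3-fold, the glutathione transferase gene GSTF2 (AT4G02520) 106-fold, the zinc finger gene ZAT10 (AT1G27730) 32.7-fold and WOX5 14.3-fold. LAX2 fell 8.96-fold and CYCB2;4 (AT1G76310) 13.8-fold. Of 18 stress genes 12 rose and of 21 mitotic genes 13 fell, or 15 and 19 adjusted over the list alone (adjusted p = 0.00044 for both with an estimated correlation).

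**Figure D4:**
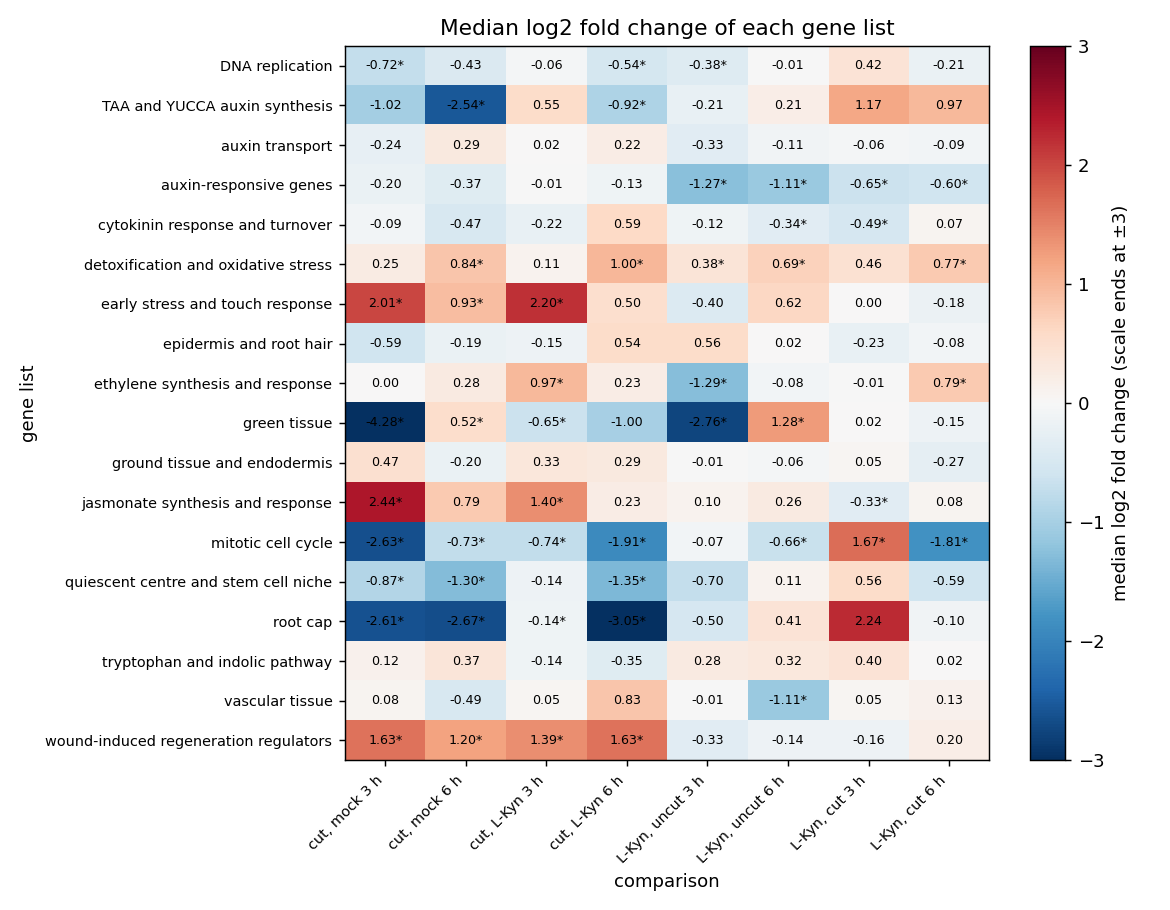
Median log2 fold change (colour and printed value, scale ending at 3 in each direction) of each fixed gene list (y axis) in 8 comparisons (x axis) of all 18 libraries without the set term, with a star where camera at the preset correlation gave an adjusted p under 0.05. The mitotic list lies at -2.63 after cutting in mock tips at 3 h and at -1.81 with L-Kyn in cut tips at 6 h, and 0 of the stars held with an estimated correlation.

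The last comparisons asked whether the effect of L-Kyn differed between cut and uncut tips. EdgeR's test of that difference called 0 genes at 3 h (1568 with an unadjusted p under 0.05, and 21 by DESeq2) and 0 at 6 h (419 with an unadjusted p under 0.05, and 0 by DESeq2). Without mock uncut replicate 3 the 3 h count was 90, and without mock cut 3 h replicate 3 it was 1. The count of 90 cannot be told apart from the set, as mock uncut tips are then of set A alone. Without L-Kyn cut 3 h replicate 1 the group holds only the library near uncut tips, so that setting may not measure L-Kyn in cut tips. The mitotic list differed at 6 h in the fit of all 18 libraries (median -1.07, 0 of 21 lower adjusted over the list alone, camera adjusted p = 0.000407, and adjusted p = 0.698 with an estimated correlation). It differed in the set-matched fit too (median -1.20, 1 of 21 lower adjusted over the list alone, and adjusted p = 0.0448 with an estimated correlation).

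Across 16354 genes, which are not independent replicates, the responses to cutting with and without L-Kyn, from groups that share no library, correlated with r = 0.351 at 3 h and 0.591 at 6 h. With the set term and without the library labelled L-Kyn cut 3 h replicate 2, the values were 0.506 and 0.554. The 3 h value was -0.262 without L-Kyn cut 3 h replicate 1 and 0.545 without the library labelled replicate 2. The L-Kyn responses of uncut and cut tips correlated with r = -0.0673 at 3 h (0.0369 in the set-matched fit) and 0.376 at 6 h (0.249 in that fit). Genes higher after cutting in mock tips at 3 h had a median log2 fold change of 0.02 with L-Kyn in cut tips at 6 h (653 genes, limma camera p = 0.959 with an estimated correlation), and genes lower after cutting a median of -0.14 (965 genes, limma camera p = 0.670). Chosen and tested in the set-matched fit, the medians were 0.33 (limma camera with an estimated correlation, p = 0.0193) and -0.27 (limma camera p = 0.0256). Genes higher and lower after cutting at 6 h in that fit (31 and 62 genes) had medians of 0.32 and -0.10 with L-Kyn in cut tips at 3 h (limma camera with an estimated correlation, p = 0.131 and 0.757). The auxin transport, epidermis and ground tissue lists were called by camera at the preset correlation in 0 of the 11 comparisons in the fit of all 18 libraries, with lowest adjusted p of 0.231, 0.231 and 0.300.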

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

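The tests of explanations in this part were chosen only after the results were seen, except the splits of the libraries and the test of the mitotic list without 1 library at a time. That mitotic test was run in the set-matched fit, itself chosen after seeing the data, on a list called there. The tests of the difference between the L-Kyn effects in cut and uncut tips were fixed before the data were examined.

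The effect of L-Kyn differed between cut and uncut tips for 3 lists at 3 h in the fit of all 18 libraries, for DNA replication (median 0.56, camera adjusted p = 0.0283, and adjusted p = 0.537 with an estimated correlation), green tissue (median 3.59, camera adjusted p = 0.00673, and adjusted p = 0.537 with an estimated correlation) and mitotic genes (median 1.87, camera adjusted p = 0.000539, and adjusted p = 0.537 with an estimated correlation). The DNA replication call was lost with adjusted p = 0.415 without the library labelled L-Kyn cut 3 h replicate 2, 0.0850 without L-Kyn uncut 3 h replicate 2, 0.111 without mock cut 3 h replicate 2, 0.0589 without mock cut 3 h replicate 3 and 0.109 without mock uncut replicate 3. The green tissue call was lost with adjusted p = 0.0811 without the library labelled L-Kyn cut 3 h replicate 2, 0.0589 without mock cut 3 h replicate 3 and 0.114 without mock uncut replicate 1. The mitotic call was lost with adjusted p = 0.964 without the library labelled L-Kyn cut 3 h replicate 2 and 0.0505 without mock uncut replicate 3. The library labelled L-Kyn cut 3 h replicate 2 had values near those of uncut tips, and without it the mitotic median turned to -0.28 and the DNA replication and green tissue medians were 0.33 and 1.18. The DNA replication median was 0.85 and 0.37 without L-Kyn uncut 3 h replicate 1 and 2. With the set term and without the library labelled L-Kyn cut 3 h replicate 2, the medians were 0.24 for DNA replication, -0.88 for green tissue and 0.04 for mitotic genes (camera adjusted p = 0.627, 0.686 and 0.475). At 6 h it differed for the cytokinin list (median 0.57, camera adjusted p = 0.0164, and adjusted p = 0.129 with an estimated correlation). It also differed for green tissue (median -1.42, camera adjusted p = 8.43e-06, and adjusted p = 0.319 with an estimated correlation), mitotic (median -1.07, camera adjusted p = 0.000407, and adjusted p = 0.698 with an estimated correlation) and vascular genes (median 0.70, camera adjusted p = 0.000705, and adjusted p = 0.129 with an estimated correlation). The cytokinin call was lost with adjusted p = 0.0776 without L-Kyn cut 6 h replicate 1, 0.112 without mock cut 6 h replicate 2, 0.0545 without mock uncut replicate 1 and 0.0762 without mock uncut replicate 2. The cytokinin median was 0.93 and 0.97 without L-Kyn cut 6 h replicate 1 and 3, 1.00 without L-Kyn uncut 6 h replicate 1 and 1.13 without mock cut 6 h replicate 1. The green tissue median was -0.71 without mock cut 6 h replicate 2 and -2.77 without mock uncut replicate 1, and the vascular median was 1.1 without L-Kyn cut 6 h replicate 1. The difference at 6 h was also called in the set-matched fit for mitotic genes (median -1.20, and adjusted p = 0.0448 with an estimated correlation). The responses to cutting at 3 h and 6 h differed for 150 genes in the set-matched fit by edgeR.

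For some named genes every library of a comparison lay on one side and every library of the matching comparison on the other. This rule is no test, and edgeR's test of the difference called 0 genes at 3 h (1568 with an unadjusted p under 0.05, 21 by DESeq2) and 0 at 6 h (419 and 0). LHY was at 1.35 CPM in mock uncut, 17.1 in mock cut, 10.7 in L-Kyn uncut and 4.91 in L-Kyn cut tips at 3 h. RGF3 was at 66.3 CPM in mock uncut, 36.9 in L-Kyn uncut, 0 in mock cut and 31.8 in L-Kyn cut tips at 3 h, the last with 0.210 and 63.4 CPM in its libraries. HDR was at 25.4, 62.2, 98.0 and 65.7 CPM in the same groups. The L-Kyn cut means at 3 h of these genes include the library labelled replicate 2, whose values lie near those of uncut tips. At 6 h HCA2 was at 3.62 CPM in mock uncut, 1.71 in L-Kyn uncut, 7.39 in mock cut and 16.3 in L-Kyn cut tips, TI1 at 11.8, 1.76, 95.2 and 172 CPM and PRN at 6.70, 0.987, 39.2 and 87.7 CPM in these groups.

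The library labelled L-Kyn cut 3 h replicate 2 lay near the uncut libraries, and on a scale from uncut (0) to mock cut tips at 3 h (1), over genes called in other libraries at 6 h, its higher position was -0.133. Material that was not cut may account for this, as it needs a position of at most 0.25. A mixture of cut and uncut tips in similar shares is argued against by a position of -0.155 in summed CPM of genes lower after cutting. L-Kyn holding back the response is argued against by L-Kyn cut 3 h replicate 1, at 1.3 on genes higher after cutting. Its Spearman correlation over genes was 0.940 to 0.975 with the L-Kyn uncut 3 h libraries. It was 0.894 to 0.928 with the mock uncut libraries and 0.879 with L-Kyn cut 3 h replicate 1. Its profile was thus nearest that of L-Kyn uncut tips at 3 h. A wrong label and a swap with a library not analysed here stay open.

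The libraries split into 2 sets that cross the groups in mock uncut tips alone, so the set term rests on replicate 3 against replicates 1 and 2. RNA from green tissue in set A stays open, as 8 of 10 green tissue genes were lower in set B and 375 genes were called higher there by edgeR, but from 1 library of that set. Time of day stays open, as 0 of 9 clock genes differed by edgeR between these 3 libraries, with 1 in set B (PRR9 log2 difference 4.35 ± 1.57 SE). LHY was at 17.1, 10.7 and 4.91 CPM in mock cut, L-Kyn uncut and L-Kyn cut tips at 3 h, against 1.75, 1.39 and 2.22 CPM at 6 h. In mock uncut tips, where the sets cross, LHY was at 1.505 and 0.922 CPM in set A and 1.608 CPM in set B. LHY thus did not follow the set there, and its 3 h values cannot tell the set from the time of treatment. Fewer distinct molecules in set B stay open, as 11 genes lay at 5 CPM or more in each set A library and under 1 CPM in each set B library, too few to exclude it. Outside mock uncut tips the set follows the time of treatment, so a biological difference with time stays open there and was not tested apart from the set. On the scale from uncut to mock cut tips at 3 h, mock uncut replicate 3 lay at -0.624 on genes higher after cutting. L-Kyn uncut 3 h libraries lay at 0.131 to 0.196. On genes lower after cutting these values were -0.0793, and -0.0195 to 0.0510. A deviation of that replicate was not tested apart from the set or from L-Kyn.

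Mitotic genes were lower with L-Kyn in cut tips at 6 h in the set-matched fit (median -1.76). A single library carrying this is argued against by an estimated-correlation p of at most 0.000665 without each of the 5 libraries in turn (limma). A smaller share of meristem in the pieces collected stays open, because the DNA replication list had a median of -0.171 (0.147 SE) but the stem cell niche list had -0.86 ± 0.59 SE, near the -0.88 that is 50% of the mitotic median. A difference in time after the cut, which the labels give for mock cut tips alone, stays open and was not tested. An effect of L-Kyn, the difference that the design names, stays open and was not tested apart from that share or that time.

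The comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. For cutting in mock tips at 3 h the real split called 1618 genes, 1 of the 10 splits called as many, and the highest other split called 1177. That split puts mock uncut replicate 3 with mock cut replicates 1 and 2, all of set B, and edgeR called 537 genes within set B. For L-Kyn in uncut tips at 3 h the real split called 0 genes by edgeR (1480 with an unadjusted p under 0.05, 118 by DESeq2). With a real count of 0 each of the 10 splits calls as many, so that count decides nothing. The highest other split called 42, with mock uncut replicate 3 beside L-Kyn uncut replicates 1 and 3, all of set B, which points to a structure of the samples.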

How the results depend on the processing

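The tests with the set term, without the library labelled L-Kyn cut 3 h replicate 2, with both changes (the set-matched fit) and within 1 set were chosen after the results were seen. With RLE factors each of the 18 main results stayed within the bounds set for it, and 1 list call of 62 was lost. Outside the ranges, the counts of genes called given here moved by over 1.5 times, and the cause was not tested. The comparison of 6 h with 3 h crosses the sets, so it has no value within 1 set.

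DESeq2 called 34 genes for cutting in mock tips at 6 h, 293 for 6 h against 3 h, 118 and 57 for L-Kyn in uncut tips at 3 h and 6 h, 39 and 48 for L-Kyn in cut tips, 57 and 707 for cutting with L-Kyn and 21 for the difference at 3 h. With no filter edgeR called 3, 155, 24, 5, 15, 1, 44 and 201 for the first 8 of these. The compared groups alone gave 243 for cutting in mock tips at 3 h, 66 for 6 h against 3 h, 2 and 37 for L-Kyn at 6 h in uncut and cut tips and 997 for cutting with L-Kyn at 6 h.

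The set term gave 1 for cutting in mock tips at 6 h, 12 for 6 h against 3 h, 5 for L-Kyn in uncut tips at 3 h, 3 in cut tips at 6 h, and 34 and 343 for cutting with L-Kyn. Without that library the counts were 55, 185, 3, 2, 339 and 560, and 5 for L-Kyn in uncut tips at 6 h. With both changes they were 93 for cutting in mock tips at 6 h, 22 and 1 for L-Kyn in uncut tips, 19 in cut tips at 6 h, and 562 and 1138 for cutting with L-Kyn. Within 1 set they were 537 and 217 for cutting in mock tips, 3 and 42 for L-Kyn in uncut tips, 55 in cut tips at 6 h, 262 and 1766 for cutting with L-Kyn and 1 for the difference at 6 h.

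With 1 library left out the counts ran from 557 to 2467 and 0 to 1 for cutting in mock tips, from 1 to 48 for 6 h against 3 h, and from 0 to 452 and 0 to 2 for L-Kyn in uncut tips. They ran from 0 to 386 for L-Kyn in cut tips at 3 h, 0 to 339 and 0 to 25 for cutting with L-Kyn and 0 to 233 for the difference at 3 h. The upper ends for L-Kyn in cut tips and for the difference at 3 h came without L-Kyn cut 3 h replicate 1. Those ends rest on the library near uncut tips alone. The upper ends of 2467 and 452 came without mock uncut replicate 3, where cutting or L-Kyn cannot be told apart from the set. List calls ran from 52 to 74. They fell from 62 of 198 to 0 with an estimated correlation and 24 by fry. Correlations across genes of the responses to cutting ran from -0.262 to 0.545 at 3 h, lowest without L-Kyn cut 3 h replicate 1, and 0.455 to 0.603 at 6 h. Those of the responses to L-Kyn ran from -0.134 to -0.0152 and 0.257 to 0.418, and became 0.0369 and 0.249 with both changes and 0.440 at 6 h with the stricter filter. Medians of cut-responsive genes under L-Kyn ran from -0.146 to 0.175 and -0.309 to 0.0332, and were 0.33 and -0.27 with both changes.

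Lists that turned with both changes were detoxification in 6 h against 3 h (-0.300), green tissue in the difference at 3 h (-0.884), and jasmonate (0.0288) and mitotic genes (-0.482) with L-Kyn in cut tips at 3 h. Leaving out L-Kyn cut 3 h replicate 1 or the library labelled replicate 2 gave the ends of these ranges of medians: -0.0895 to 2.20 for jasmonate, -3.0 to 0.0523 for mitotic and -3.06 to 0.605 for root cap genes in cutting with L-Kyn. They were -1.91 to 0.0251 for jasmonate and -0.483 to 2.53 for mitotic genes with L-Kyn in cut tips, and -0.281 to 2.63 for mitotic genes in the difference at 3 h.

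Deviations from group means showed no clear pairing of libraries by replicate number. Over 48 pairs with the same number the median correlation of deviations was 0.0177 (-0.248 to 0.318), with 42 under 0.1. Over 90 pairs with different numbers it was -0.00898 (-0.367 to 0.298), with 76 under 0.1. In groups of 2 libraries the deviations mirror each other, so pairing cannot be excluded in this way. With the replicate block the counts were 22 for 6 h against 3 h and 11 for cutting with L-Kyn at 6 h, and it changed 12 calls of named genes and 1 of a list. RLE factors moved the median of all genes in the difference at 6 h from 0.05 to 0.11. Depth limits folds of genes with few counts, as for WOX5, with 12 counts in total over mock uncut tips and 5 over L-Kyn uncut tips at 3 h.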

Other observations

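LHY (AT1G01060), a morning gene of the circadian clock, was at 1.35 ± 0.373 CPM in mock uncut tips. It was at 10.7 ± 0.0650 CPM in L-Kyn uncut and 17.1 ± 9.98 in mock cut tips at 3 h, and 1.39 ± 0.0620 and 1.75 ± 0.726 CPM in L-Kyn uncut and mock cut tips at 6 h (mean ± SD, n = 2 or 3). Its values in the L-Kyn cut libraries at 3 h were 5.47 and 4.34 CPM, and at 6 h its mean was 2.22 ± 0.944 CPM. TOC1, an evening clock gene, was at 61.0 ± 20.6 CPM in mock uncut, 31.8 ± 4.93 in mock cut tips at 3 h and 40.3 ± 5.61 in mock cut tips at 6 h. GI, another, was at 34.0 ± 2.17, 20.6 ± 6.28 and 26.9 ± 1.07 CPM. The labels give no clock time, and these genes were chosen after their values were seen.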
